A study of Mus musculus with 5 samples.

How the data were processed

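Gene expression was measured by RNA sequencing in 5 libraries from the mammary glands of adult virgin mice. Per the labels' protocols, the mice had lost their ovaries and carried hormone pellets for 14 days, and about 50 cells per library were collected by flow sorting. The cells were lysed in guanidine, and their RNA was precipitated, reverse-transcribed and amplified by PCR with a modified Smart-seq2 protocol developed for small tissue samples (Geo-seq). Libraries were sequenced on an Illumina HiSeq instrument. Smart-seq2 libraries of this kind are not described in the labels as carrying molecular identifiers or strand information, so amplified copies and antisense transcripts were treated as not separable.

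Reads were processed with TopHat2 2.0.4, Cufflinks 2.0.2 and Cuffdiff 2.0.2 on the mouse genome build mm10, per the submitters' processing notes. The gene annotation is not given in the sources used here. The deposited table holds log2(FPKM + 1) per gene and library, where FPKM is the number of fragments scaled by transcript length and by the mapped fragments of the library. The authors' log base and offset were read from the values. With base 2, between 99.69% and 99.78% of the values above 1 in a library return to an FPKM of 6 significant digits, as Cufflinks prints it, within 0.02 of the last digit. With base e the share is 3.97% to 4.48%, and with base 10 it is 3.64% to 4.58%. The table has 12311 rows, and the highest FPKM of every gene is above 1 (lowest 1.0003). A gene under that level in all 5 libraries is therefore not analysed here.

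Genes whose names had been turned into dates by a spreadsheet (18 rows, 0.085% to 0.119% of the summed FPKM of a library) were left out, and 12293 remained. Of these, 10953 carry a symbol that is current in RefSeq. About 184 rows join the names of several genes, such as Hba-a1Hba-a2, and were kept as the authors wrote them. Expi, 1600029D21Rik and Mkl1 are older names of Wfdc18, Plet1 and Mrtfa. How fragments were divided between near-identical copies is not given in the sources used here. Values of the heat shock pair Hspa1a and Hspa1b, of ribosomal proteins and of keratins with pseudogenes (Krt8, Krt18) are uncertain to that extent. Gene positions come from the GENCODE annotation of GRCm38, the assembly of mm10.

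FPKM values are not counts, so no count model was used. The main test was limma 3.58.1 with an intensity trend on log2(FPKM + 1), so the pseudocount was 1. All 5 libraries entered 1 fit with a mean per group, over the 10626 genes with a mean FPKM of 1 or more. The residual spread rests on 2 degrees of freedom, and the prior added 1.65. P-values are two-sided and Benjamini-Hochberg adjusted over the genes of a comparison, and a call is an adjusted p under 0.05. The luminal group has 1 library, which was assumed to vary like the others. A log2 difference on this scale understates the change of low genes, and none is given against a group listed at 0 in all its libraries.

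Gene lists were tested with limma's camera on the same fit, with a preset correlation between genes of 0.01. There were 29 lists, of which 26 had at least 3 members past the filter on mean FPKM, and Benjamini-Hochberg adjustment ran over the lists of a comparison. Beside this, camera was run with a correlation estimated from the data, and fry tested whether the members of a list moved, on balance, one way. With an estimated correlation no list passed in any of the 3 comparisons. That form of camera rests on the 2 residual degrees of freedom, which the preset form does not, so few lists could pass. In LdBC against basal the tight junction list had an estimated correlation of -0.00585, below the preset one. It still did not pass (camera with Benjamini-Hochberg adjusted p = 0.301). For a list with an estimate at or below the preset one, failing this form therefore does not show that its call came from correlated genes. Other lists had higher estimates, such as 0.772 for ribosomal proteins and 0.610 for hormone-sensing genes. Basal identity had 0.204 and oxidative phosphorylation 0.201. For such lists the p-values with the preset correlation may be too small. For each list the members passing, among those past the filter, were counted over all genes and adjusted over the list alone. Lists share members and are not independent. Vim, Snai2 and Sparc stand in the epithelial to mesenchymal transition and basal identity lists. The stem cell list shares Procr, Lgr6, Sox10 and Dll1 with basal identity and Sox9 and Tspan8 with luminal progenitors. Calca, Areg, Prlr, Pgr, Tnfsf11, Wnt4, Stc2 and Ramp3 stand in the hormone target and hormone-sensing lists.

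The groups, the tests, the gene lists, the rule for named genes and the alternatives were written down before the data were examined. Named genes are, per comparison and direction, the 10 with the largest difference among calls whose groups do not overlap and whose higher group has a mean FPKM of at least 5. Predicted and unnamed genes are left out. Where fewer than 10 passed, genes that met all but the adjusted p, with a gap of at least 1 log2 unit between the nearest libraries, fill the list and are given as values. A set of anchor genes (among them Krt5, Krt14, Krt8, Krt18, Esr1 and Elf5) and up to 4 members of each list with the largest differences are named as well. Some genes that these rules cover are not reported here.

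A further measure placed LdBC between basal and luminal cells. Genes differing by at least 2 log2 units between 1 basal library and the luminal library were selected, and LdBC was then compared with the other basal library. The roles of the basal libraries were swapped and both results are given. The luminal library could not be held out, since there is 1, and the simulated LdBC were drawn like basal cells only.

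The fit was tested on simulated data with 50 changed genes per size among 10626. In the LdBC to basal comparison it recovered 0% of differences of 2 log2 units, 20% at 4, 54% at 6 and 66% at 8, with 1 false call. In the LdBC to luminal comparison the shares were 0%, 0%, 22% and 46%, with 0 false calls. In the basal to luminal comparison they were 0%, 0%, 10% and 44%, with 0 false calls. The simulation gave all groups the same mean, changed 200 genes with a mean above 4 log2 units and shuffled the spreads among genes. In the real data the basal to luminal fit called 343 genes higher and 540 lower, at log2 differences from 1.08 upward. The simulated shares are therefore not the power of the reported tests.

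Read totals are not in the deposited FPKM, so absolute depth is unknown and no counting interval is given. The FPKM ratio of low genes between libraries gathers at the ratio of what 1 fragment is worth. By this estimate, which rests on peaks of 11 to 38 genes, the libraries were sequenced 1.21 (LdBC replicate 1), 1.22 (LdBC replicate 2), 1.5 (Basal replicate 1) and 1.64 times (Basal replicate 2) as deeply as the luminal library. The number of cells, about 50, also limits what a library can show. Alternatives tried were pseudocounts of 0.1 and 5, no filter and a mean FPKM of at least 5, quantile normalization, median-of-ratios scaling, limma without trend and with a robust prior. Each library was also left out in turn, and the shared replicate numbers were used as a block. Scaling moved the median difference of all genes from 0.20 to -0.09 (LdBC minus basal), from 0.01 to 0.27 (LdBC minus luminal) and from -0.13 to 0.37 (basal minus luminal) with median-of-ratios factors, and to 0.01, 0.04 and 0.05 with quantile normalization. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.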

Results

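RNA was profiled in 3 populations of mammary epithelial cells from ovariectomized mice that had received hormone pellets. All were sorted as lineage-negative and CD24-positive. Luminal cells, which line the ducts, were CD29low and GFP-positive (1 library). Basal cells, which include the contractile myoepithelial cells, were CD29hi and TdTomato-positive (2 libraries). The third population, named luminal-derived basal cells (LdBC), was CD29hi like basal cells and GFP-positive like luminal cells (2 libraries). The series asks which transcripts differ between these populations. The labels do not say whether the libraries of a group come from separate animals. Limma p-values therefore measure only the spread between these libraries, which may be technical, moderated by a prior taken from all genes. No spread between luminal libraries enters them. Camera p-values with the preset correlation set the members of a list against the other genes, under an assumed correlation of 0.01. However small, they are not a measure of the spread between libraries.

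Of 12293 genes, 8041 were above 0 in the luminal library, 9201 and 10627 in LdBC replicates 1 and 2, and 10979 and 10834 in Basal replicates 1 and 2. The most abundant transcript was B2m, a component of class I antigen presentation, in the luminal library (46216 FPKM). It was Krt18 in both LdBC libraries and Apoe in both basal libraries. In the luminal library 162 genes were listed at 0 that had an FPKM of at least 10 in each of the other 4 libraries. The same count was 26 for LdBC replicate 1, 0 for LdBC replicate 2, and 2 and 5 for Basal replicates 1 and 2. None of 76 genes for RNA polymerase II, proteasome, splicing and translation initiation subunits was at 0 in any library. Across genes, which are not independent replicates, Spearman's rho was 0.868 between the basal libraries and 0.728 between the LdBC libraries. It lay between 0.651 and 0.712 for LdBC with basal, and was 0.526 and 0.589 for LdBC with luminal and 0.504 and 0.503 for basal with luminal. The transcripts of the sorted proteins followed the gates and are not findings. Itgb1 (CD29) had an FPKM of 22.9 in luminal, 63.7 and 83.7 in LdBC and 77.3 and 93.4 in basal libraries, and Cd24a had 488, then 203 and 162, then 109 and 95.2.

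The first comparison asks how GFP-positive CD29hi cells differ from ordinary basal cells. LdBC carried the keratins of luminal epithelium at a far higher level than basal cells, while their basal keratins and contractile transcripts were present at a lower level. Krt18, a keratin of simple epithelia (chromosome 15, 102028180 to 102032027, plus strand), had an FPKM of 14101 and 12798 in LdBC and of 194 and 172 in basal cells. It was the only gene past the threshold over all genes (log2 difference 6.19, SE 0.14, limma with Benjamini-Hochberg adjusted p = 0.0435, higher in 2 of 2 LdBC libraries). Krt18 did not pass with a pseudocount of 0.1, with median-of-ratios scaling, in limma without trend or without the luminal library. Its partner Krt8 (chromosome 15, 101996698 to 102004482, minus strand) had 8153 and 6685 against 441 and 324. Krt14, a keratin of basal cells (chromosome 11, 100203162 to 100207548, minus strand), had 751 and 992 in LdBC against 2682 and 2206. Acta2, smooth muscle actin of myoepithelial cells (chromosome 19, 34241090 to 34255590, minus strand), had 349 and 820 against 3941 and 3800. These 3 passed only when adjusted over the list alone. All log2 differences are on the log2(FPKM + 1) scale, which understates the change of low genes.

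Genes of luminal identity were higher in LdBC as a group. Of 30 members, 19 passed as higher and 0 as lower when adjusted over the list alone, and 1 over all genes (median difference 3.03, camera with Benjamini-Hochberg adjusted p = 2.21e-09; adjusted p = 0.301 with an estimated correlation). Examples are the tight junction claudins Cldn3 (766 and 647 against 8.86 and 0) and Cldn7 (617 and 708 against 12.5 and 0.699) and the luminal keratin Krt19 (1547 and 1729 against 19.8 and 5.25). The adhesion molecule Epcam had 2303 and 1871 against 387 and 337. Tight junction and polarity genes moved the same way, with 13 of 21 higher and 0 lower over the list alone and 0 over all genes (median 1.63, camera with Benjamini-Hochberg adjusted p = 3.75e-06; adjusted p = 0.301 with an estimated correlation). The polarity gene Crb3 had 115 and 78.5 in LdBC against 3.81 and 1.90 in basal cells, and Ocln (occludin) had 73.8 and 117 against 4.25 and 0.896. The claudins Cldn1, Cldn3, Cldn4, Cldn7 and Cldn8 stand in both lists.

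Basal and contractile genes were lower in LdBC as groups in camera. The basal identity list did not pass in fry (Benjamini-Hochberg adjusted p = 0.0523). Of 26 basal identity genes, 0 were higher and 11 lower over the list alone, and 0 over all genes (median -2.17, camera with Benjamini-Hochberg adjusted p = 1.04e-11; adjusted p = 0.301 with an estimated correlation). The largest differences among the 11 were in the membrane peptidase Mme (0 and 0.357 against 27.5 and 12.1) and the chemokine Cxcl14 (55.8 and 75.5 against 581 and 650). Krt5 (chromosome 15, 101707070 to 101712898, minus strand) had 29.4 and 20.0 against 206 and 201. Trp63, the gene of the basal transcription factor p63 (chromosome 16, 25683763 to 25892102, plus strand), had 0 and 3.57 against 24.4 and 20.2 and did not pass. Snai2, which encodes the transcription factor Slug, had 36.6 and 49.2 against 99.2 and 121, and Sox10, with 37.0 and 35.9 against 22.7 and 29.7, did not pass. Of 22 contractile genes, 0 were higher and 12 lower over the list alone, and 0 over all genes (median -1.86, camera with Benjamini-Hochberg adjusted p = 5.93e-09; adjusted p = 0.301 with an estimated correlation). Tagln (172 and 172 against 1953 and 1878), Myl9 (127 and 309 against 1699 and 1511) and Cnn1 (38.4 and 117 against 440 and 517) were among the 12. Of 18 basement membrane and hemidesmosome genes 0 passed over all genes or over the list alone (median -1.31, camera with Benjamini-Hochberg adjusted p = 0.000109; adjusted p = 0.301 with an estimated correlation). The laminin gene Lamb3 had 0 and 15.1 against 82.0 and 88.5, and the median of the list was -0.72 without LdBC replicate 1.

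Genes of luminal progenitors and of milk secretion were also higher in LdBC in camera. Neither list passed in fry (Benjamini-Hochberg adjusted p = 0.0523 and 0.0676). Of 20 progenitor genes, 9 were higher and 2 lower over the list alone, and 0 over all genes (median 1.64, camera with Benjamini-Hochberg adjusted p = 0.0017; adjusted p = 0.389 with an estimated correlation, and 0.0877 with the preset one without LdBC replicate 1). Elf5, a transcription factor of alveolar development, had 45.8 and 27.9 in LdBC and was listed at 0 in both basal libraries. Cd14 had 1106 and 896 against 17.1 and 7.95, and Tspan8 had 71.0 and 90.9 against 4.20 and 11.6. The chemokine Cxcl2 and the protease inhibitor Slpi were the 2 lower members. Of 23 milk and alveolar genes, 11 were higher and 0 lower over the list alone, and 0 over all genes (median 3.08, camera with Benjamini-Hochberg adjusted p = 1.2e-05; adjusted p = 0.389 with an estimated correlation). The casein genes Csn1s2a (612 and 3136 against 22.7 and 0) and Csn3 (2629 and 1298 against 51.4 and 1.63) passed over the list alone, as did Expi, which encodes a whey acidic protein family member (10613 and 10246 against 303 and 128). The casein genes Csn1s1 (904 and 2056 against 99.3 and 0) and Csn2 (2341 and 5232 against 731 and 11.8) did not pass. Expi stands in the luminal identity list as well.

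**Figure D1:**
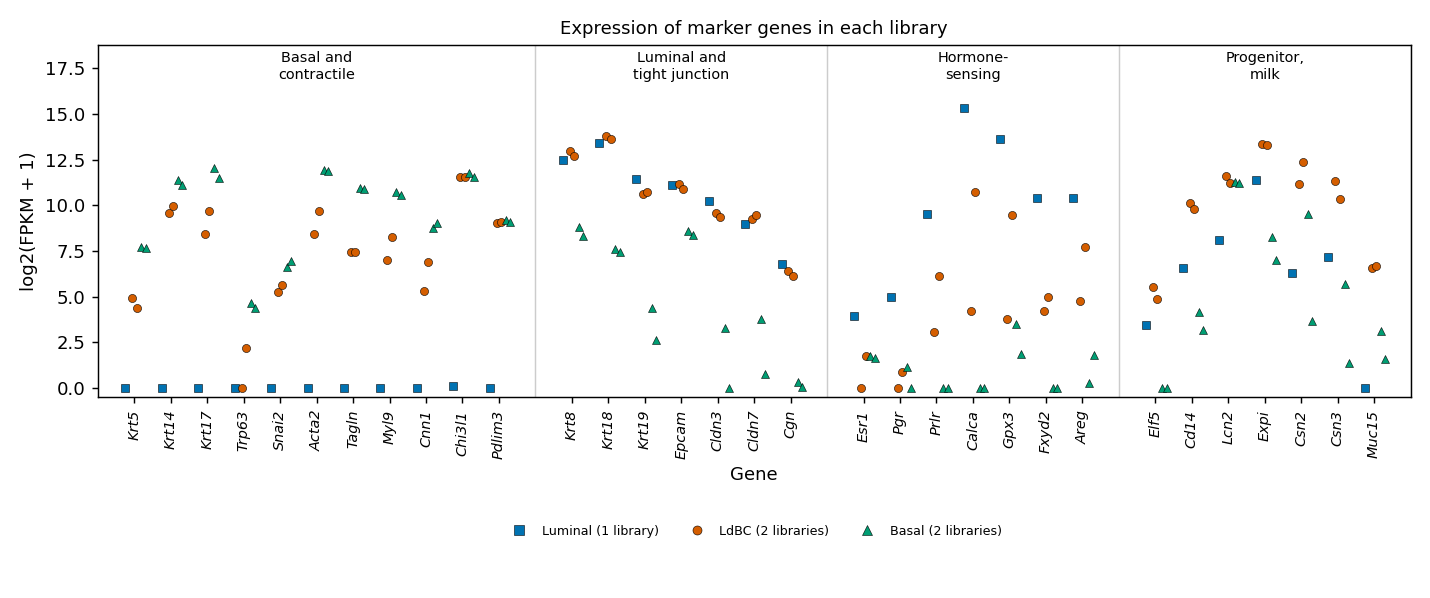
Expression of marker genes, 1 symbol per library, on a log2(FPKM + 1) scale (vertical axis), with genes along the horizontal axis and squares for luminal, circles for LdBC and triangles for basal libraries. Krt18 lies at 14101 and 12798 FPKM in LdBC and at 194 and 172 in basal libraries, and Krt14 at 751 and 992 in LdBC, at 2682 and 2206 in basal libraries and at 0 in the luminal library.

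Hormone-sensing luminal genes differed between the LdBC libraries. Of 23 members, 1 (the ion transport regulator Fxyd2, 17.3 and 30.1, listed at 0 in both basal libraries) was higher and 0 lower over the list alone, and 0 passed over all genes (median 1.28, camera with Benjamini-Hochberg adjusted p = 0.0228; adjusted p = 0.706 with an estimated correlation). The median was 2.56 without LdBC replicate 1 and 0.00 without LdBC replicate 2, where the call ended (camera with Benjamini-Hochberg adjusted p = 0.473). By the same test the call also ended without Basal replicate 1 (adjusted p = 0.0598) and without Basal replicate 2 (0.0747). Calca, a calcitonin gene, had 17.5 in LdBC replicate 1 and 1721 in replicate 2, and was listed at 0 in both basal libraries. The receptor gene Prlr had 7.41 and 68.6. Esr1 and Pgr, the estrogen and progesterone receptor genes, had 0 and 2.43 and 0 and 0.863 in LdBC, against 2.33 and 2.17 and 1.24 and 0 in basal cells.

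Among the remaining lists, 14 genes of epithelial to mesenchymal transition (EMT) had a median of -1.37, with 1 higher (the integrin Itgb6) and 5 lower (among them S100a4, Sparc, Snai1 and Snai2) over the list alone and 0 over all genes (camera with Benjamini-Hochberg adjusted p = 0.000505; adjusted p = 0.409 with an estimated correlation). Of 26 Wnt signalling genes, 0 were higher and 1, the ligand Wnt11, lower over the list alone and 0 over all genes (median -0.88, camera with Benjamini-Hochberg adjusted p = 0.00257; adjusted p = 0.301 with an estimated correlation). Of 16 glycolysis genes, 8 were higher and 1 lower (Pgam1) over the list alone and 0 over all genes (median 0.76, camera with Benjamini-Hochberg adjusted p = 0.00231; adjusted p = 0.301 with an estimated correlation). The aldolase gene Aldoc had 264 and 336 against 16.7 and 11.9, the median was 0.37 with median-of-ratios scaling, and quantile normalization ended the call (0.35, camera with Benjamini-Hochberg adjusted p = 0.143). The 52 oxidative phosphorylation genes had a median of 0.65, with 0 passing over the list alone or over all genes (camera with Benjamini-Hochberg adjusted p = 4.55e-07; adjusted p = 0.409 with an estimated correlation), and 0.26 with median-of-ratios scaling and 0.18 with quantile normalization. The 63 ribosomal protein genes had a median of 0.58, with 0 passing over the list alone or over all genes (camera with Benjamini-Hochberg adjusted p = 1.04e-11; adjusted p = 0.53 with an estimated correlation). That median was 0.19 with median-of-ratios scaling and 0.07 with quantile normalization, where the call ended (camera with Benjamini-Hochberg adjusted p = 0.175). The median over all genes was 0.20 as deposited.

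Markers of other cells moved with this comparison too. Of 10 fibroblast genes in the table, Col1a2, Col3a1, Col5a1, Col6a2 and Pdgfra had a mean FPKM under 1 and were not tested. Of the 5 past the filter, 0 were higher and 4 lower in LdBC over the list alone and 0 over all genes (median -2.09, camera with Benjamini-Hochberg adjusted p = 0.00053; adjusted p = 0.358 with an estimated correlation). The collagen-binding proteoglycan gene Dcn had 26.8 and 67.0 in LdBC, 275 and 268 in basal cells and 305 in the luminal library. The endothelial marker Cldn5 had 110 in Basal replicate 1, 0 in Basal replicate 2 and 0 and 0.199 in LdBC. The endothelial list (median -1.54, adjusted p = 0.12) passed without Basal replicate 2 (median -2.78, camera with Benjamini-Hochberg adjusted p = 5.39e-05). The pericyte list (median -1.81, adjusted p = 0.101) passed without Basal replicate 1 (-1.63, 0.0381) or without Basal replicate 2 (-2.04, 0.0396), by camera with Benjamini-Hochberg adjustment. The lists for proliferation (median 0.46, mean 0.31, camera direction down, adjusted p = 0.873), mammary stem cells (-0.75, 0.126), Notch signalling (0.29, 0.844), estrogen and progesterone targets (0.86, 0.358), immediate early and stress genes (-0.20, 0.516), interferon response (0.08, 0.844), class II antigen presentation (-0.71, 0.844) and fatty acid and sterol synthesis (0.27, 0.303) did not pass in camera with Benjamini-Hochberg adjustment. Nor did those for immune (1.14, 0.303) and Schwann cells (1.20, 0.889). The median of the interferon genes was above 0 while the direction in camera was down. The proliferation list passed without LdBC replicate 1 (median -0.68, camera with Benjamini-Hochberg adjusted p = 0.0465). Over all genes 0 members of the lists named in this paragraph passed. Adjusted over the list alone, Lgr5 and Inhba were lower and Tspan8 and Sox9 higher in the stem cell list, and Igfbp4 was lower and Elf5, Xbp1 and Ctsd higher among the hormone targets. Fads2, Scd1 and Acly (fatty acid synthesis), Klf6 (stress), Cd52 (immune) and Mbp (Schwann) were higher, Cnp (Schwann) was lower, and of the pericyte list Notch3 was higher and Des and Cox4i2 lower. Notch3 and Des belong to other lists as well. Of 19 Notch genes, 3 were higher (among them Hes1 and Notch3) and 2 lower (Jag1 and Hes6) over the list alone, with the target Hes1 at 141 and 159 against 14.9 and 7.31 and the receptor Notch3 at 6.46 and 8.47 against 0.201 and 0.0115. No member of the proliferation, interferon, class II or endothelial lists passed over the list alone.

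Over all genes, limma with Benjamini-Hochberg adjustment called 1 gene higher and 0 lower in LdBC than in basal cells, with 2127 genes at an unadjusted p under 0.05. In 3246 genes both LdBC libraries lay above both basal libraries and in 1973 below, together 49.1% of genes, where chance gives 33.3% for libraries on 1 scale. Median-of-ratios log2 factors were 0.14 and 0.22 for LdBC and -0.18 and -0.24 for basal libraries. A difference in scale can therefore add to the excess and to the imbalance. Among genes that did not pass, the naming rule gave Csn1s2a (8.16), Cldn3 (7.81), Csn3 (7.30), Krt19 (7.16), Cldn7 (7.11), Csn1s1 (7.09), the proton pump subunit Atp6v1b1 (7.08) and Fcgbp (7.03). On the other side it gave Lgals1 (-5.96), Rnu12 (-5.51), Actg2 (-5.46), Pdgfrl (-5.24), Mfap2 (-5.20), Il17b (-4.97), Ctps (-4.95) and Krt15 (-4.94). Calca, also named by the rule, was listed at 0 in both basal libraries (17.5 and 1721 in LdBC). Them5 (40.2 and 22.5 in basal cells) and Fgf21 (31.3 and 26.3) were listed at 0 in both LdBC libraries. Without LdBC replicate 1 or 2, Basal replicate 1 or 2, or the luminal library, 0 genes passed in limma, with 2522, 2993, 1289, 1240 and 2124 at an unadjusted p under 0.05. Quantile normalization gave 15 higher and 2 lower (88.2% higher, where the deposited values gave 100%), and median-of-ratios scaling gave 0 (1931 unadjusted). List medians with low genes moved with the pseudocount, and at a pseudocount of 5 the EMT, Wnt and fibroblast medians were -0.60, -0.36 and -0.74, and at 0.1 they were -2.36, -1.66 and -4.18. At 5 the contractile median was -1.03 and the basement membrane median -0.78, and the hormone-sensing median was 2.82 at 0.1 and 0.65 at 5. The Wnt median was -0.28 with a mean FPKM of at least 5.

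**Figure D2:**
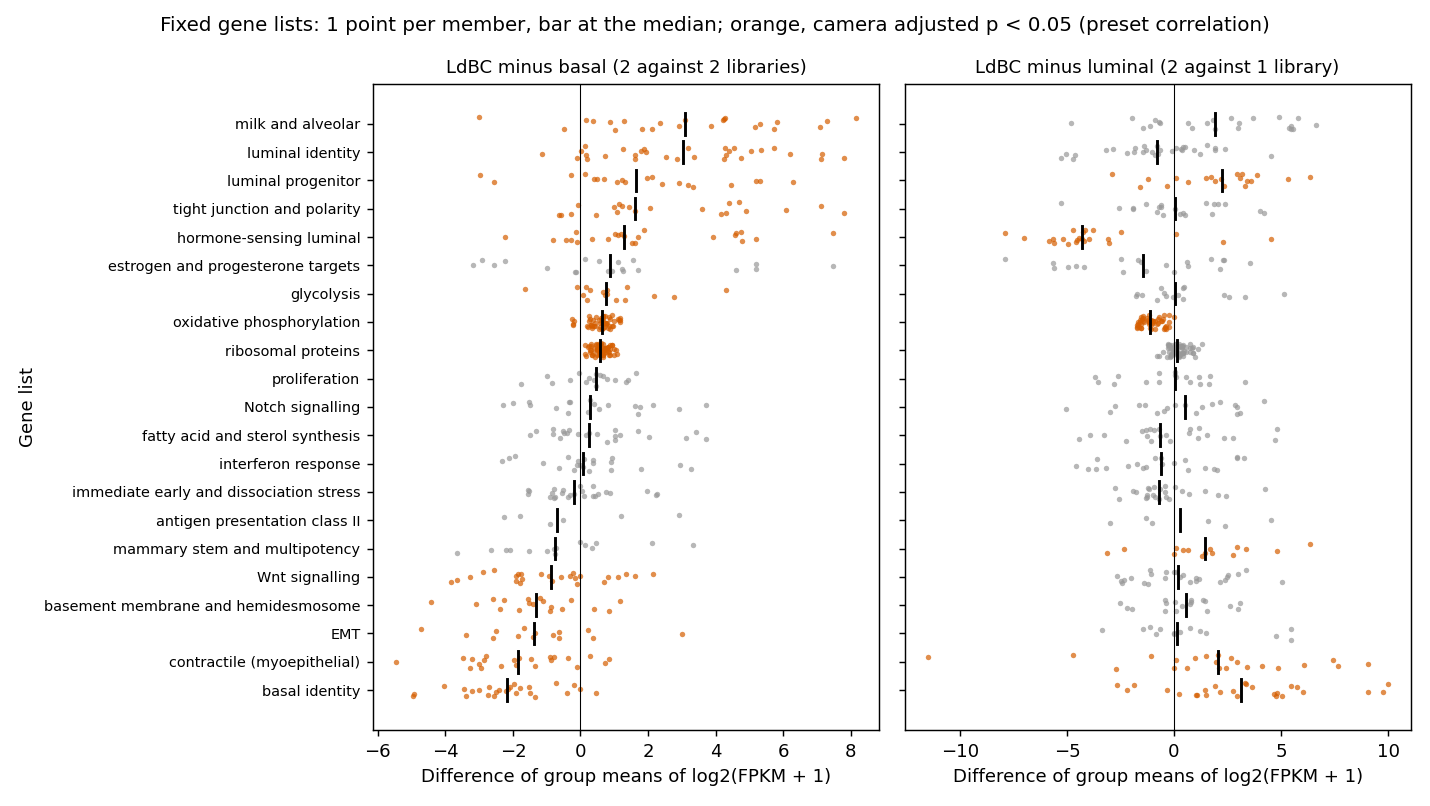
Differences of group means of log2(FPKM + 1) (horizontal axes) for members of fixed gene lists (vertical axis), LdBC minus basal on the left and LdBC minus luminal on the right, with a point per gene, a black bar at the median, and in orange the lists whose camera adjusted p was under 0.05 with the preset correlation. None kept that call with an estimated correlation, a form of the test that rests on 2 residual degrees of freedom. The luminal identity median lies at 3.03 against basal and -0.77 against luminal cells, and the basal identity median at -2.17 and 3.14.

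The second comparison asks how LdBC differ from the luminal cells that share their GFP label. LdBC held basal keratin, contractile and other basal transcripts that were listed at 0 or nearly so in the luminal library, and its hormone-sensing transcripts had a lower median. That list passed in camera with Benjamini-Hochberg adjustment (adjusted p = 0.000502) but not with an estimated correlation (adjusted p = 0.94), and 1 of its 23 members, Fxyd2, was lower over all genes. Luminal keratins and Epcam were abundant in both. Chi3l1, a secreted chitinase-like protein, had 3053 and 3035 in LdBC and 0.0989 in the luminal library (log2 difference 11.44, SE 0.18, limma with Benjamini-Hochberg adjusted p = 0.0116, higher in 2 of 2 libraries). Krt14 (751 and 992, adjusted p = 0.0259 in limma with Benjamini-Hochberg adjustment), Pdlim3 (523 and 537, 0.0215) and Tagln (172 and 172, 0.0252) were listed at 0 in the luminal library. Krt18 had 10755 in the luminal library (difference 0.32, SE 0.17), Krt8 had 5708 (0.37, SE 0.28) and Epcam 2215 (-0.09, SE 0.22), and none of these passed.

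Other named genes higher in LdBC were Apoe (859 and 1916 against 0.28), Krt17 (349 and 835), Acta2 (349 and 820), Myl9 (127 and 309), Mgp (130 and 261) and the growth factor gene Ctgf (102 and 227), the last 5 listed at 0 in the luminal library. Each had an adjusted p of 0.044 in limma with Benjamini-Hochberg adjustment. Lower in LdBC were Pcp4 (2889 in the luminal library), Slc44a4 (255), Folr2 (125), Enho (97.2), Fam183b (93.4), Grhl3 (99.6) and Ube2t (64.6), which were listed at 0 in both LdBC libraries. Plac8 (-7.55), Gmpr (-7.21) and the histone gene Hist3h2ba (-7.83) were below 1 FPKM in LdBC. Gmpr had an adjusted p of 0.0469 and the other 9 had 0.044 in limma with Benjamini-Hochberg adjustment. Slc44a4 was listed at 0 in both basal libraries too, so its p-value rests on the prior from other genes, not on a spread of its own.

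Of 26 basal identity genes, 7 were higher and 0 lower in LdBC over all genes, and 15 higher and 1 lower (the cadherin Cdh3) adjusted over the list alone (median 3.14, camera with Benjamini-Hochberg adjusted p = 9.25e-06; adjusted p = 0.798 with an estimated correlation). Snai2 had 36.6 and 49.2 against 0, and Sox10 had 37.0 and 35.9 against 0.352. Trp63 was listed at 0 in the luminal library and in LdBC replicate 1. Of 22 contractile genes, 5 were higher (Acta2, Myl9, Tagln, Cnn1 and Smtn) and 1 lower (Pcp4, a calmodulin-binding protein) over all genes, and 11 and 3 adjusted over the list alone (median 2.06, camera with Benjamini-Hochberg adjusted p = 0.00238; adjusted p = 0.798 with an estimated correlation).

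Hormone-sensing genes had a median of -4.30 over 23 members (camera with Benjamini-Hochberg adjusted p = 0.000502; adjusted p = 0.94 with an estimated correlation). Over all genes Fxyd2 was lower (1341 in the luminal library, 17.3 and 30.1 in LdBC) and Id2, a transcriptional inhibitor, was higher (7.32 against 178 and 210). Adjusted over the list alone, 1 was higher and 3 lower, Fxyd2, Pgr and Tbx3. Calca had 41755 in the luminal library and 17.5 and 1721 in LdBC, and the antioxidant enzyme Gpx3 had 12671 against 12.6 and 703, with neither passing. Esr1 had 14.3 and Pgr 31.2 in the luminal library.

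Luminal progenitor genes were higher in LdBC, 3 of 20 over all genes (Tspan8, Lbp and Lcn2) with 0 lower, and 7 and 0 adjusted over the list alone (median 2.25, camera with Benjamini-Hochberg adjusted p = 0.00238; adjusted p = 0.798 with an estimated correlation). The iron-binding lipocalin Lcn2 had 3092 and 2356 against 270, and Elf5, with 45.8 and 27.9 against 9.94, did not pass. Lbp and Lcn2 were also called higher in basal than in luminal cells, and Lcn2 differed little between LdBC and basal cells (log2 difference 0.13). Tspan8 had 4.20 and 11.6 in basal cells and 0 in the luminal library. The list as a whole did not pass in basal against luminal cells (median 0.18, camera with Benjamini-Hochberg adjusted p = 0.604). The mammary stem cell list had 3 of 15 members higher over all genes (Tspan8, Sox10 and Cd44), 5 higher over the list alone and 0 lower by either count (median 1.45, camera with Benjamini-Hochberg adjusted p = 0.0425; adjusted p = 0.798 with an estimated correlation). Its median was 2.35 without LdBC replicate 1. It did not pass in camera with Benjamini-Hochberg adjustment without LdBC replicate 2 (median 0.26, adjusted p = 0.168), with quantile normalization (0.0538), with median-of-ratios scaling (0.0655) or without trend (0.0525). Of 52 oxidative phosphorylation genes, 0 were higher and 2 (Ndufb2 and Ndufa1) lower over all genes and 0 and 14 adjusted over the list alone (median -1.11, camera with Benjamini-Hochberg adjusted p = 3.2e-10; adjusted p = 0.798 with an estimated correlation). That median was -0.65 with quantile normalization and -0.71 with median-of-ratios scaling.

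The milk and alveolar list did not pass (median 1.94, camera with Benjamini-Hochberg adjusted p = 0.0625), although 3 of 23 members, Muc15, Plin2 and Trf, were higher over all genes and the same number adjusted over the list alone. In camera with Benjamini-Hochberg adjustment it passed with a pseudocount of 5 (adjusted p = 0.0369), a mean FPKM of at least 5 (0.0239), quantile normalization (0.0101), without Basal replicate 1 (0.0229) and without Basal replicate 2 (0.0186). Plin2, a lipid droplet protein, had 526 and 440 in LdBC against 60.0, and the iron carrier Trf had 4412 and 4821 against 723. Luminal identity (median -0.77, adjusted p = 0.581), tight junction (0.04, 0.839), basement membrane (0.56, 0.71), EMT (0.15, 0.793), Wnt (0.18, 0.866), Notch (0.51, 0.623) and proliferation genes (median 0.06, mean -0.28, 0.864) did not pass in camera with Benjamini-Hochberg adjustment. Nor did estrogen and progesterone targets (-1.44, 0.193), stress (-0.71, 0.272), interferon (-0.63, 0.272), class II (0.28, 0.974), glycolysis (0.06, 0.866) or fatty acid and sterol genes (-0.67, 1.00). The ribosomal list (median 0.15, adjusted p = 0.136, 0 members past the threshold over all genes or over the list alone) passed in camera with Benjamini-Hochberg adjustment with quantile normalization (0.44, 3.14e-07) and median-of-ratios scaling (0.55, 1.67e-06), and with a pseudocount of 5 (0.045) or a mean FPKM of at least 5 (0.041). Of the lists of other cells, fibroblast (0.00, 0.864), endothelial (0.16, 1.00), pericyte (0.00, 0.757), immune (1.47, 0.71) and Schwann cell genes (1.39, 0.212) did not pass in camera with Benjamini-Hochberg adjustment. The mean was -0.40 for fibroblast and -0.06 for endothelial genes. Over all genes Mmp2 and Snai2 (EMT), Pfkl and Slc2a1 (glycolysis) and Sqle (sterol synthesis) were higher and Hes6 (Notch), Ctsd (hormone targets) and Oas2 (interferon) lower. Adjusted over the list alone these passed too, with Sparc, Marveld3, Maml2, Notch3, Pard6b, Tjp3, H2-Ab1, Pfkp, Fads1, Cd52 and Cnp higher and Cdh2, Wfdc2 and Tpi1 lower.

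Over all genes, limma with Benjamini-Hochberg adjustment called 219 genes higher and 207 lower in LdBC than in luminal cells, with 3318 at an unadjusted p under 0.05. Of the higher genes 116 were listed at 0 in the luminal library, and of the lower genes 133 were listed at 0 in both LdBC libraries. The groups did not overlap in 76.7% of genes, where chance gives 66.7% for libraries on 1 scale. By the estimate from low FPKM values the luminal library was the shallowest, and it had the most genes at 0, and with 1 library its own spread is not measured. Without LdBC replicate 1 or 2 or Basal replicate 1 or 2, 0 genes passed in limma, with 3899, 4182, 2105 and 2107 at an unadjusted p under 0.05. Without a filter on low values 4 were higher and 0 lower. A pseudocount of 0.1 gave 865 higher and 310 lower, a pseudocount of 5 gave 135 and 348, and the robust prior 127 and 17. The balance of higher and lower calls thus rests on the setting. The basal identity median was 5.34 with a pseudocount of 0.1 and 1.59 with 5. The stem cell median was 3.02 and 0.60 with these pseudocounts, and the progenitor median 1.43 with 5.

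The third comparison, of basal with luminal cells, gives the ordinary difference between the gates. Basal cells expressed basal keratins and the contractile apparatus, and luminal cells expressed simple keratins, hormone-sensing genes and more transcripts of oxidative phosphorylation. With an estimated correlation the hormone-sensing and oxidative phosphorylation lists did not pass (camera with Benjamini-Hochberg adjusted p = 0.612 and 0.396), and the oxidative phosphorylation median of -1.55 was -0.69 with quantile normalization and -0.76 with median-of-ratios scaling. Chi3l1 (3497 and 3053 against 0.0989, log2 difference 11.54, SE 0.18) and Tagln (1953 and 1878 against 0) both had an adjusted p of 0.00935 in limma with Benjamini-Hochberg adjustment. Apoe (7198 and 6393 against 0.28), Acta2 (3941 and 3800), Krt17 (4258 and 2896), Krt14 (2682 and 2206), Myl9 (1699 and 1511), Mgp (1033 and 895), Cxcl14 (581 and 650) and Pdlim3 (583 and 536) were higher as well (adjusted p from 0.0139 to 0.0349 in limma with Benjamini-Hochberg adjustment), the last 7 listed at 0 in the luminal library. Lower in basal cells were Pcp4 (-8.23), Krt19 (-7.91), Ly6a (-7.88) and, listed at 0 in both basal libraries, Fxyd2 (1341 in the luminal library), Hp (883), Prlr (743), Cited1 (482), Hist3h2ba (258), Slc44a4 (255) and Wfdc12 (234), with adjusted p from 0.0349 to 0.0485 in limma with Benjamini-Hochberg adjustment. Slc44a4 was also listed at 0 in both LdBC libraries, so its p-value rests on the prior from other genes.

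Of 26 basal identity genes, 12 were higher and 0 lower over all genes, and 20 and 0 adjusted over the list alone (median 4.61, camera with Benjamini-Hochberg adjusted p = 3.24e-12; adjusted p = 0.396 with an estimated correlation). Krt5 had 206 and 201 against 0. Of 22 contractile genes, 9 were higher and 1 (Pcp4) lower over all genes, and 16 and 2 adjusted over the list alone (median 3.25, camera with Benjamini-Hochberg adjusted p = 3.9e-06; adjusted p = 0.396 with an estimated correlation). Of 18 basement membrane genes, 0 passed over all genes and 4 were higher over the list alone, among them Col4a1 and Lama3 (median 2.04, camera with Benjamini-Hochberg adjusted p = 0.0178; adjusted p = 0.396 with an estimated correlation). The stem cell list had 2 of 15 higher over all genes (Sox10 and Cd44), and 7 higher and 1 lower over the list alone (median 2.65, camera with Benjamini-Hochberg adjusted p = 0.00358; adjusted p = 0.396 with an estimated correlation). The EMT list had 3 of 14 higher (Sparc, Snai2 and Mmp2) and 1 lower (Itgb6) over all genes, and 5 and 2 over the list alone (median 1.48, camera with Benjamini-Hochberg adjusted p = 0.0396; adjusted p = 0.603 with an estimated correlation). That call, by camera with Benjamini-Hochberg adjustment, ended without LdBC replicate 1 (adjusted p = 0.0565), LdBC replicate 2 (0.0563) or Basal replicate 1 (0.0596), and with quantile normalization (0.0567), median-of-ratios scaling (0.0755), a pseudocount of 0.1 (0.073) or no trend (0.0642).

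Of 30 luminal identity genes, 0 were higher and 9 lower in basal cells over all genes, and 0 and 22 adjusted over the list alone (median -3.89, camera with Benjamini-Hochberg adjusted p = 2.75e-07; adjusted p = 0.396 with an estimated correlation). Krt8 had 441 and 324 against 5708, and Krt19 had 19.8 and 5.25 against 2735. Hormone-sensing genes had 1 of 23 higher (Id2) and 4 lower (Fxyd2, Prlr, Cited1 and Ly6a) over all genes, and 1 and 16 adjusted over the list alone (median -6.32, camera with Benjamini-Hochberg adjusted p = 0.000196; adjusted p = 0.612 with an estimated correlation). Tight junction genes had 5 of 21 lower over all genes, including Crb3 and Ocln, and 3 higher and 10 lower over the list alone (median -1.84, camera with Benjamini-Hochberg adjusted p = 0.0178; adjusted p = 0.396 with an estimated correlation). The tight junction call, by camera with Benjamini-Hochberg adjustment, ended without LdBC replicate 1 (adjusted p = 0.068) or LdBC replicate 2 (0.0632), whose spread enters the fit, and the median was -1.07 with median-of-ratios scaling. Oxidative phosphorylation genes had 0 higher and 15 of 52 lower over all genes, and 0 and 46 adjusted over the list alone (median -1.55, camera with Benjamini-Hochberg adjusted p = 4.78e-13; adjusted p = 0.396 with an estimated correlation). The cytochrome oxidase subunit Cox7c had 232 and 152 against 1224. The 63 ribosomal genes had a median of -0.43 as deposited (camera with Benjamini-Hochberg adjusted p = 0.00683; adjusted p = 0.811 with an estimated correlation), with 0 passing over the list alone or over all genes, and medians of 0.36 and 0.38 with median-of-ratios scaling and quantile normalization, where they passed in the opposite direction, higher in basal cells (camera with Benjamini-Hochberg adjusted p = 0.00827 and 4.05e-05). The call as deposited, by camera with Benjamini-Hochberg adjustment, ended with a mean FPKM of at least 5 (adjusted p = 0.132), without trend (0.0822) and without Basal replicate 2 (median -0.26, 0.0854).

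Wnt genes (median 1.86, adjusted p = 0.0753, and 0.0412 with a mean FPKM of at least 5) and estrogen and progesterone targets (-2.36, 0.0608, and 0.0368 with median-of-ratios scaling or 0.0226 without a filter) did not pass in camera with Benjamini-Hochberg adjustment. Neither did the lists for progenitor (median 0.18, adjusted p = 0.604), milk and alveolar (-1.23, 0.465), proliferation (-0.21, 0.85), Notch (0.11, 0.662), stress (-0.74, 0.348), interferon (-0.80, 0.465), class II (0.58, 0.85), glycolysis (-0.44, 0.369) and fatty acid and sterol genes (-1.08, 0.449), or those for fibroblast (1.96, 0.102), endothelial (1.96, 0.449), pericyte (1.81, 0.141), immune (0.00, 0.963) and Schwann cells (0.00, 0.487). In camera with Benjamini-Hochberg adjustment and without Basal replicate 2, the fibroblast (2.59, 0.00684), endothelial (3.63, 0.00781) and pericyte lists (2.04, 0.0456) passed, as did the fibroblast list without Basal replicate 1 (1.43, 0.0497) or without a filter (1.48, 0.0164). Means and medians differed for Schwann (1.59) and immune genes (-0.04). Over all genes Wif1 and Wnt11 (Wnt), Lbp and Lcn2 (progenitor), Maml2, Pfkl, Sqle and Cnp were higher. Prlr, Ctsd and Sgk1 (hormone targets), Expi and Folr1 (milk), Aurka, Hes1, Hspa1a, Klf6, Oas2, Aldoc, Tpi1, Pkm, Acly and Fads2 were lower. Adjusted over the list alone, 3 hormone targets were higher and 10 lower, 4 progenitor genes higher and 3 lower, 2 Notch genes higher and 3 lower, 2 glycolysis genes higher and 3 lower, 1 fatty acid and sterol gene higher and 3 lower, and 1 class II gene higher and 2 lower. Adipocyte genes (3 in the table, 2 past the filter), erythroid genes (1 and 1) and mitochondrially encoded genes (0 in the table) had under 3 members past the filter and were not tested.

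Over all genes, limma with Benjamini-Hochberg adjustment called 343 genes higher and 540 lower in basal than in luminal cells, with 4049 at an unadjusted p under 0.05. Of these, 197 of the higher genes were listed at 0 in the luminal library and 132 of the lower genes in both basal libraries. The groups did not overlap in 88.3% of genes, where chance gives 66.7% for libraries on 1 scale. The share of calls that were higher was 38.8% as deposited, 61.8% with median-of-ratios scaling (352 higher, 218 lower) and 53.7% with quantile normalization (425 higher, 367 lower). Without LdBC replicate 1 or 2 or Basal replicate 1 or 2, 0 genes passed in limma, with 4871, 4887, 2284 and 2245 at an unadjusted p under 0.05. With pseudocounts of 0.1 and 5 the basal identity median was 7.66 and 2.56, the stem cell median 5.74 and 1.30 and the EMT median 3.65 and 0.66. The contractile median was 5.11 with 0.1, and with 5 the hormone-sensing median was -4.06 and the basement membrane median 1.03. With a mean FPKM of at least 5 the EMT and basement membrane medians were 4.80 and 1.23.

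The last measure asks where LdBC lie on the genes that separate basal from luminal cells. The single luminal library both selected the genes and served as the luminal end point, so its own noise, including the 162 genes listed at 0 that had an FPKM of at least 10 in the other libraries, enlarges the luminal distance, and no nearer side is read from these values. Over genes higher in basal cells (2300 and 2167 in the swaps), the median of the LdBC mean minus the held-out basal library was -0.33 and -0.46 log2 units, while the luminal library lay at -2.79 and -2.86. Over genes higher in luminal cells (2146 and 2292), LdBC lay at 0.55 and 0.49 and the luminal library at 2.95 and 2.78. LdBC replicate 1 had 0.23 and 0.24 on the latter genes and replicate 2 had 0.85 and 0.72, so the spread between libraries and swaps (SD 0.323) was large beside the mean of 0.52. The selecting basal library itself differed from the held-out one by 0.26 and 0.16 on the first set and by 0.00 and -0.23 on the second. Both LdBC libraries lay on the luminal side of the held-out basal library in 40.6% and 45.5% of the genes higher in basal cells and in 44.7% and 45.1% of those higher in luminal cells. For libraries that are alike, on 1 scale and without ties, chance gives 33.3%. No test was made, since genes are not replicates, and simulated LdBC drawn like basal cells gave medians of 0.11 to 0.18 on the first set and -0.13 to 0.00 on the second. The simulated values were centred on the mean of both basal libraries, the selecting one included, so they share part of its shift. They are no baseline for a basal library independent of the selection. On the genes higher in basal cells the mean of the swaps was -0.39 (SD 0.133), -0.25 without LdBC replicate 1, -0.76 with quantile normalization, -0.67 with median-of-ratios scaling and -0.15 with a mean FPKM of at least 5. On the genes higher in luminal cells the mean of the swaps was 0.79 without LdBC replicate 1 and 0.23 without replicate 2, 0.30 with median-of-ratios scaling and 0.47 with quantile normalization.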

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

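All alternatives reported in this part were planned before the data were examined. Of the main counts and positions, 80 values were within 1.5 times or 1 SD of the reported ones or stayed at 0, and 27 moved. A further 30 were counts of genes or lists that fell to 0, and 1 was a count that rose from 0. For single lists 1036 values kept direction and call, or passed in neither setting whatever their direction. Another 69 lost the call, 22 gained it and 2 reversed, where a reversal was counted only if at least 1 of the settings passed. For named genes 553 values kept direction and side of the threshold, 205 lost the call, 2 gained it and 0 reversed. Where no cause is given, the cause was not tested. The number of genes called in limma with Benjamini-Hochberg adjustment rests on 2 residual degrees of freedom, and depth and about 50 cells per library limit what can be said of low genes.

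In the LdBC to basal comparison 0 genes were higher with a pseudocount of 0.1 (2029 unadjusted), median-of-ratios scaling (1931), limma without trend (1987) and without the luminal library (2124). There were 2 with a mean FPKM of at least 5, where fewer genes are tested, and with the robust prior, and 15 higher and 2 lower with quantile normalization. In the LdBC to luminal comparison 865 genes were higher with a pseudocount of 0.1, 135 with 5, 4 without a filter, 485 with a mean FPKM of at least 5, 367 without trend and 127 with the robust prior. Lower were 348 with a pseudocount of 5, 0 without a filter (3378 unadjusted in both directions), 129 with quantile normalization, 106 with median-of-ratios scaling and 17 with the robust prior. In the basal to luminal comparison 1101 genes were higher with a pseudocount of 0.1, 202 without a filter and 682 with a mean FPKM of at least 5. Lower were 876 with a pseudocount of 5, 286 without a filter, 939 with a mean FPKM of at least 5, 218 with median-of-ratios scaling and 325 without trend. Leaving out an LdBC or basal library left 1 residual degree of freedom, and the counts of genes passing in those fits, given above, are not interpreted.

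The replicate numbers shared by LdBC and basal libraries were used as a block, which gave 0 genes higher and 0 lower in limma (1710 unadjusted, 1 residual degree of freedom) and 14 lists. Deviations from the group means of libraries with the same number had a Pearson correlation of 0.0115 over genes (Spearman 0.00654), so no shared deviation was seen. Noise within each library can hide such a deviation. Whether libraries with the same number share an animal, sort or day therefore stays open.

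Of the 14, 6 and 10 lists past the threshold in the LdBC to basal, LdBC to luminal and basal to luminal comparisons, 0, 0 and 0 passed in camera with an estimated correlation. That form rests on the 2 residual degrees of freedom. With fry 6, 0 and 8 lists passed. In LdBC against basal these were the contractile, basement membrane, luminal identity, Wnt, tight junction and glycolysis lists. Basal identity and progenitor (fry with Benjamini-Hochberg adjusted p = 0.0523 for both), milk (0.0676), fibroblast (0.0797) and oxidative phosphorylation genes (0.0806) did not pass. Nor did the ribosomal (0.143), EMT (0.263) and hormone-sensing lists (0.326). Leaving out 1 library gave 13 to 15, 5 to 7 and 8 to 12 lists. The ribosomal protein list in the basal to luminal comparison reversed from -0.43 to 0.38 with quantile normalization and 0.36 with median-of-ratios scaling. Both also moved the median of all genes upward in this comparison.

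The position of LdBC on genes higher in basal cells, -0.39, was -0.55 with a pseudocount of 5, -0.15 with a mean FPKM of at least 5, -0.76 with quantile normalization and -0.67 with median-of-ratios scaling. It ranged from -0.45 to -0.25 with 1 LdBC library left out. With genes selected at 3 log2 units it was -0.50, and 0.61 on genes higher in luminal cells.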

Other observations

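All tests in this part were chosen after the result they concern was seen.

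A group of genes stood at least 4-fold higher in both LdBC libraries than in each of the other 3 libraries, on the log2(FPKM + 1) scale. It held 136 genes, of which 26 would pass the filter on mean FPKM by the other 3 libraries alone and 110 passed it only with the LdBC libraries. Among the 26 were the monocyte receptor gene Cd14 (1106 and 896 FPKM in LdBC, 93.3 in the luminal library and 17.1 and 7.95 in basal libraries) and Plin2, which coats lipid droplets (526 and 440, then 60.0, then 65.1 and 61.3). Among the 110 were Spp1, a secreted phosphoprotein (81.0 and 182 FPKM in LdBC, listed at 0 in the luminal and both basal libraries), Wfdc3 (34.8 and 65.0, listed at 0 elsewhere) and the interleukin antagonist Il1rn (38.4 and 31.2, listed at 0 elsewhere). The peptide hormone gene Cck had 209 and 236 in LdBC, 0 in the luminal library and 3.76 and 0 in basal libraries, and the carbonic anhydrase gene Car2 had 116 and 172, then 0.0926, then 2.29 and 0.0567. The genes named here were chosen after their values were seen.

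Of 23 milk and alveolar genes, 7 were in this group (Csn1s2a, Csn3, Csn1s1, Cel, Muc15, Btn1a1 and Plin2). Groups of as many genes, drawn 10000 times from those of like level in the other 3 libraries, held 0.587 on average (one-sided permutation test, Benjamini-Hochberg adjusted p = 0.0014, not a limma or camera test). Of 20 luminal progenitor genes, 5 were in it (Basp1, Cd14, Notch3, Tspan8 and Kit), where the draws held 0.568 (adjusted p = 0.0014 in the same test with Benjamini-Hochberg adjustment). Both unadjusted p-values, 0.0001, are the smallest that the draws can give. No other list passed. Genes are not independent replicates, so these p-values describe these 5 libraries. Of the members named, Cel, Btn1a1, Basp1, Notch3 and Kit passed the filter only with the LdBC libraries, and the draws came from the same filtered genes. Both lists were also already higher in LdBC than in basal cells in these libraries. The permutation p-values are therefore no separate support.

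One technical account of the group is chance, since libraries with many genes listed at 0 may share high values by accident, while a shared sort, day or animal of the LdBC libraries and a difference of the cell population were not tested. For the 26 genes, 1000 shuffles of LdBC replicate 2 among genes of like level in the other 3 libraries gave a median of 1 and at most 5, which argues against chance. For the 110 genes the shuffles gave a median of 142 and at most 160, but there the filter keeps a low gene only where an LdBC library is high, so chance stays open, and over all genes together the shuffles gave 144 and at most 162 against 136. Loss from the other libraries of transcripts that all populations hold stays open as well. The luminal library with LdBC replicate 2 gave 114 genes, and the other 7 pairs of libraries from different groups gave 6 to 32. A pair that splits replicates must exceed its own replicates, so these low counts do not settle it. Among genes past the filter by the remaining libraries alone, the luminal library with LdBC replicate 2 gave 23 against at most 11 in shuffles. With LdBC replicate 1 it gave 14 against at most 14, and each of the other 6 gave 0 or 1. Genes at least 4-fold lower in a pair than in the other libraries numbered 213 for the luminal library with LdBC replicate 1. They numbered 73 for it with LdBC replicate 2, and 1 to 26 for the other pairs from different groups.

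LdBC held Krt8, Krt18 and Epcam at 84.5% of the luminal level or more, together with basal transcripts below the basal level, and a mixture of sorted cells may produce this. For luminal cells like those of the luminal library, the hormone-sensing genes would have to lie near the luminal level as well. Their median difference was -4.30 (quartiles -5.06 and -3.43, 23 genes), which argues against this source. For luminal cells of another kind mixed with basal cells, 34 genes abundant in basal cells should share 1 percentage of the basal level. Their median was 22.9% (13.8% in LdBC replicate 1 and 29.7% in replicate 2), and the spread between genes (interquartile range 1.40 in log2) was wider than the 0.752 that replicate noise gives, with Chi3l1 at 93.2% and 92.7% and Pdlim3 at 93.5% and 95.9%, but such luminal cells may express some of these genes themselves, so this source stays open, although the CD29hi gate should remove CD29low luminal cells and the GFP gate TdTomato-positive basal cells, unless cells stick together or spill over.

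Over 15 hormone-sensing genes at an FPKM of at least 50 in the luminal library, the median level was 8.32% of the luminal one in LdBC replicate 2 (14 genes above 1%) and 0.672% in replicate 1 (6 genes above 1%), while Ly6a (9.23% and 14.5%) and Cited4 (0% and 15.9%) went the other way. Free luminal RNA is a candidate source, and it would keep its genes in 1 ratio. Of 27 genes abundant in the luminal library and hardly seen in basal libraries and LdBC replicate 1, 9 lay more than 4-fold below the median ratio, against 4 measures of replicate noise (one-sided exact binomial p = 5.54e-06, 4.69e-08, 0.0113 and 0.113), so the noise measure chosen sets the answer. A few hormone-sensing luminal cells among about 50 are another candidate source, which the CD29hi gate should remove. The median of those genes was 5.55% of the luminal level (quartiles 0.925% and 12.6%), and with Pcp4, Slc44a4, Folr2 and Hist3h2ba listed at 0 this stays open, as does a difference between the mice or sorts of the libraries.

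Basal replicate 1 held the endothelial transcripts Cldn5 (110 FPKM), Emcn (18.3), Esam (15.2) and Pecam1 (11.3), all listed at 0 in Basal replicate 2. The luminal library held the hemoglobin pair Hba-a1Hba-a2 at 1249 FPKM.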
